A study of Bos taurus with 17 samples.

How the data were processed

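RNA from 17 pools of 10 bovine morulae (9 control, 8 with recombinant WNT5A) was extracted with an RNeasy micro kit and made into libraries with the TruSeq stranded mRNA kit, per the labels' protocols. FastQC, HISAT2, featureCounts and edgeR are named in the submitters' processing notes, with the assembly ARS-UCD1.2; their versions, trimming, strand setting and annotation release are not given in the sources used here. The authors deposited one table of RPKM values for 17167 genes, with an exon length per gene. The same table holds a log2 fold change, a log2 CPM, a likelihood ratio score, a p-value and an FDR per gene, per the file headers, and 2 columns of mean RPKM that the authors deposited were equal to the means of the libraries within 1.8e-12. No per-sample column was left unused. Groups and numbers came from the labels.

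RPKM times gene length fell on whole multiples of one step per library for 100% of values (tolerance 0.001). Multiples of this step were taken as reads, giving 34.0 to 200 M per library over the genes in the table. Sums of RPKM times kilobases were 0.946 to 1.15 M per library, so the deposited values carry the authors' own scaling of library size. A floor of 3 reads on a gene of 1 kilobase corresponded to 0.0155 to 0.0841 RPKM, and covers counting error only; the floor was highest in WNT5A library 4. Reads without molecular identifiers are not independent molecules.

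Groups, tests, gene lists and most of the alternatives were chosen before the data were examined. Because RPKM are not counts, the test was limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend and robust options, two-sided) on log2(RPKM + 1), for genes with at least 0.5 RPKM in at least 8 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. The plan had a count test for the case that counts were deposited, which was not used. Fold changes are on the log2(RPKM + 1) scale and understate changes of low genes. The filter left 12415 genes tested and 4752 not. Lists fixed in advance numbered 37, of which 36 had at least 5 tested members and were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Library measures were compared by two-sided exact permutation tests over all 24310 splits, adjusted over 8 measures. On simulated data with 12415 genes and each gene's residual spread, the WNT5A against control test recovered 43 of 100 genes with a log2 change of 1. It recovered 90 of 100 with a log2 change of 2, with 3 false calls. Residuals were shuffled between libraries separately for each gene, so shifts that many genes share in a library were not kept. The changed genes were all added together, whereas 1 gene passed in the real data. These shares therefore need not hold for the real data.

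The genes named were fixed by a rule. These were 14 genes of WNT signalling and lineage, genes past the threshold filled to 20 with the smallest unadjusted p among genes with a symbol, and for each list described the members past the threshold or else the 2 with the smallest p. Values of some genes that met the rule are not reported here. Genes named from the authors' deposited table, and libraries set apart by reads or genes detected, were chosen after their values were seen. WNT5A libraries below 100 M reads (4, 12 and 14) and control libraries with under 12000 genes detected (2, 3 and 6) were left out only in alternatives. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15. Positions, GC content and sex-linked genes were not analysed here.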

Results

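Gene expression was measured by stranded messenger RNA sequencing in 17 pools of bovine morulae, each of 10 embryos produced in vitro. Of these, 9 pools were controls and 8 had been cultured with recombinant WNT5A, a secreted ligand best known for signalling through planar cell polarity and calcium branches of the WNT pathway. The comparison asked how WNT5A altered the transcriptome of the morula, the stage at which blastomeres compact and the first lineages begin to separate. The deposited values were RPKM for 17167 Ensembl genes on the ARS-UCD1.2 assembly. Genes are named by the symbol in the deposited table, or by the Ensembl identifier where it gave none, and no chromosome positions were used here. The labels do not say whether pools came from separate fertilisation rounds, so p-values describe the spread between these pools.

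Control pools held 145 ± 13.4 M (mega) reads (SD, n = 9) and WNT5A pools 119 ± 65.8 M reads (SD, n = 8), as recovered from the RPKM values. WNT5A libraries 4, 12 and 14 had 34.0 to 52.4 M reads, whereas the other 5 had 140 to 200 M and the controls 125 to 162 M. In those 3 libraries the uncharacterised gene ENSBTAG00000051364 took 3.51% to 5.64% of all reads. Its share was at most 0.00302% in the other 5 and 0.00381% in any control. The genes that share the microRNA symbol bta-mir-2887-2 together took 0.394% to 3.98% in WNT5A libraries 4, 12 and 14. They took at most 0.00687% in the other 5 and 0.0134% in any control. Control libraries 2, 3 and 6 were apart in another way, with 10055 to 11268 genes detected against 13587 to 15430 in the other controls, at similar numbers of reads. Ribosomal protein genes took 4.86% to 6.34% of reads in these 3 controls and 2.46% to 4.94% in the other 6. Library pairs correlated at 0.810 to 0.984 on the log2 scale across genes, and no pair was identical.

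**Figure D1:**
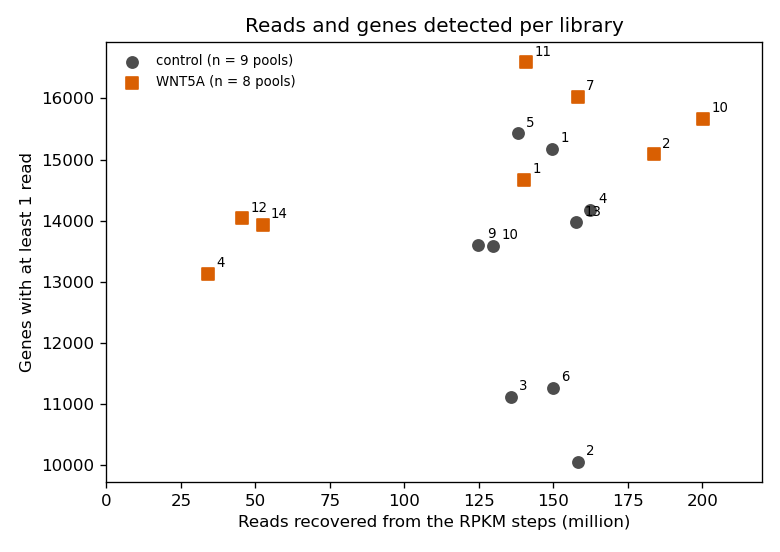
Reads recovered per library (M, horizontal axis) and genes with at least 1 read (vertical axis, not starting at 0) for 9 control pools (circles) and 8 WNT5A pools (squares), each numbered by its title. WNT5A libraries 4, 12 and 14 lie at 34.0 to 52.4 M reads, and control libraries 2, 3 and 6 at 10055 to 11268 genes.

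The 10 most abundant genes took a larger share of reads in WNT5A pools, 7.77% ± 2.95 (SD, n = 8), than in control pools, 5.74% ± 0.327 (SD, n = 9), by a two-sided exact permutation test over 24310 splits (adjusted p = 0.0461 over 8 measures). Without WNT5A libraries 4, 12 and 14 the difference shrank from 2.03 to 0.30 percentage points (adjusted p = 0.349, same exact test). It was 1.09 points without WNT5A library 12 alone (exact adjusted p = 0.101), and the call was also lost on ranks (exact adjusted p = 0.219), without control libraries 2, 3 and 6 (0.610) and when any one of 13 libraries was left out. Genes detected averaged 14893 ± 1172 (SD, n = 8) in WNT5A pools and 13156 ± 1893 (SD, n = 9) in controls, which did not pass after adjustment (exact permutation p = 0.0424, adjusted p = 0.170). Mitochondrially encoded genes took 1.51% ± 0.553 of control reads (SD, n = 9) and 1.74% ± 0.801 of WNT5A reads (SD, n = 8; exact permutation adjusted p = 0.807). Mean levels of oocyte transcripts (adjusted p = 0.830) and of cumulus and granulosa cell genes (adjusted p = 0.944) did not pass that exact test either.

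With 12415 genes tested, a single gene passed an adjusted p of 0.05 in limma. This was ENSBTAG00000027786, a gene without a symbol, which was higher in WNT5A pools at 4.81 ± 1.97 RPKM (SD, n = 8) than in controls at 0.587 ± 1.57 (SD, n = 9), a log2 change of 2.12 ± 0.35 (SE; limma adjusted p = 0.0460). It had reads in 8 of 8 WNT5A pools and in 2 of 9 controls. At an unadjusted p under 0.05 there were 913 genes, 712 higher and 201 lower with WNT5A, where a share of 0.05 of the tested genes is 621. Other random splits of the 17 libraries gave a median of 425 such genes and at most 2389. Of all tested genes 62.3% had a fitted value above 0. The fitted log2 changes of all tested genes had a median of 0.11, which became -0.01 after quantile normalization and 0.00 without control libraries 2, 3 and 6. The call of ENSBTAG00000027786 was lost when any one of 16 libraries was left out, and held (limma adjusted p = 1.1e-04) without control library 5, when SNORD15 also passed (limma adjusted p = 0.0199).

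CLDN7, which encodes the tight junction protein claudin 7, and KHDRBS3, an RNA-binding protein gene, had the clearest separation among genes with a symbol, although neither passed the threshold. CLDN7 stood at 43.7 ± 30.2 RPKM in WNT5A pools (SD, n = 8) and 15.5 ± 3.68 in controls (SD, n = 9), with a log2 change of 1.28 ± 0.27 (SE; limma adjusted p = 0.488). KHDRBS3 stood at 54.4 ± 5.47 RPKM (SD, n = 8) against 30.4 ± 10.1 (SD, n = 9), with a log2 change of 0.90 ± 0.21 (SE; limma adjusted p = 0.494). Both were above all 9 controls in each of the 8 WNT5A pools. These were the only 2 of 12415 tested genes whose groups did not overlap, and random splits give 1.02 such genes. In the 5 WNT5A libraries with more reads, CLDN7 averaged 29.4 ± 6.18 RPKM and KHDRBS3 50.9 ± 3.08 RPKM.

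The other genes with the smallest unadjusted p, none past the threshold, were mostly low in abundance. Among them FBXL14, a ubiquitin ligase subunit gene, had a log2 change of 2.16 ± 0.55, ZC3H3 1.59 ± 0.43, SNORD15 1.53 ± 0.34, MB21D2 1.48 ± 0.41, PLBD1 1.44 ± 0.32, SBF1 1.41 ± 0.40 and the homeobox gene SIX2 1.35 ± 0.34 (SE). TSHZ3 (1.24), TMEM59L (1.16), GML (1.15), AMOTL1 (1.13), KLF2 (1.12), SNX17 (1.02), NPDC1 (1.01) and GPR161 (0.97) followed, with PDPR between NPDC1 and GPR161. SPINK7 was the only one of these 20 genes with a lower value, at 0.832 ± 1.09 RPKM (SD, n = 8) against 3.44 ± 2.45 (SD, n = 9) and a log2 change of -1.27 ± 0.35 (SE; limma adjusted p = 0.673). FBXL14 averaged 47.1 RPKM in WNT5A libraries 4, 12 and 14, 14.2 in the other 5, 9.84 in 6 of the controls and 0.801 in control libraries 2, 3 and 6. ZC3H3 (10.5 against 1.81 RPKM), SBF1 (9.03 against 1.56), SNORD15 (5.38 against 1.82) and SIX2 (5.26 against 0.851) were also higher on average in these 3 WNT5A libraries than in the other 5, and the means of TSHZ3 and SNX17 were 2.88 and 2.44 times as high there. Without these 3 and control libraries 2, 3 and 6, the log2 changes of the 19 higher genes were 0.36 to 1.18, against 0.90 to 2.16 with all libraries and 0.46 to 1.87 after quantile normalization.

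**Figure D2:**
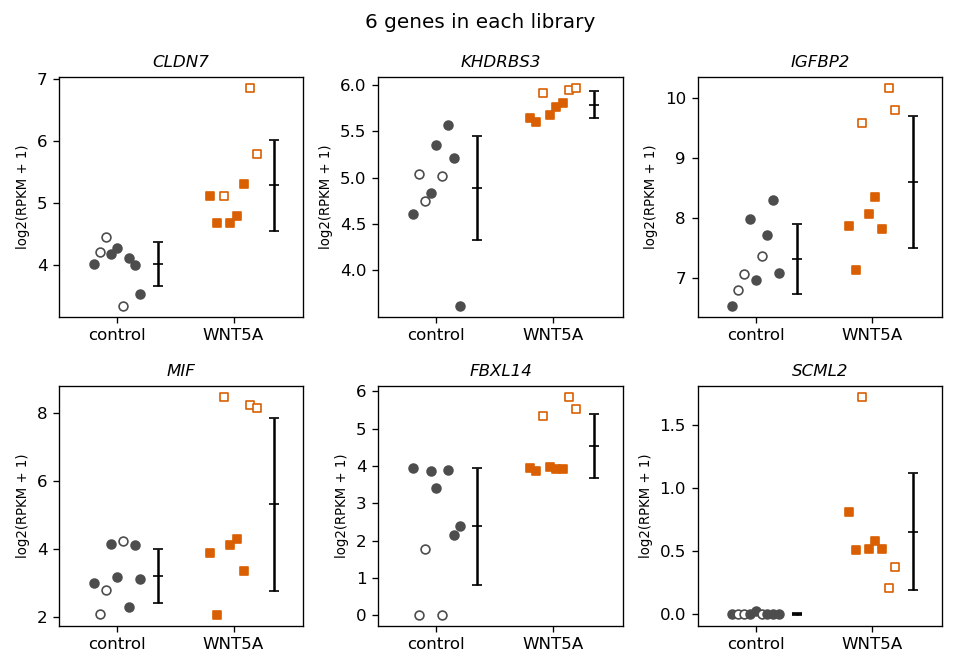
Level of 6 genes in each library as log2(RPKM + 1), in 9 control pools (circles) and 8 WNT5A pools (squares), with the mean and SD of each group at its right. Open symbols mark control libraries 2, 3 and 6 and WNT5A libraries 4, 12 and 14; CLDN7 and KHDRBS3 do not overlap between groups, and MIF is high in the 3 open WNT5A symbols alone. Axes differ between panels and do not start at 0.

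Receptors and intracellular components of WNT signalling did not pass as single genes or as lists. The WNT5A transcript itself was not tested, with reads in 5 of 9 controls and 3 of 8 treated pools. It stood at 0.763 ± 1.99 RPKM in controls (SD, n = 9), of which control library 3 held 6.05 and the other 8 averaged 0.102 ± 0.151 (SD), and at 0.357 ± 0.548 in treated pools (SD, n = 8), so that the order of the group means turned on that 1 library. The tyrosine kinase receptors of WNT5A, ROR1 and ROR2, averaged at most 0.196 RPKM in either group, and the transcription factor LEF1 averaged 0.305 RPKM in controls and 0.434 in WNT5A pools. RYK, a further WNT5A receptor, was readily detected at 8.58 ± 4.08 RPKM in controls (SD, n = 9) and 9.09 ± 2.69 in WNT5A pools (SD, n = 8), with a log2 change of 0.20 ± 0.33 (SE; limma adjusted p = 0.875). FZD5 had a log2 change of 0.38 ± 0.49, and AXIN2, a feedback target of beta-catenin, 0.13 ± 0.43 (SE; limma adjusted p = 0.834 and 0.944). Without control libraries 2, 3 and 6 RYK had -0.10 and FZD5 -0.21, and AXIN2 had -0.24 without control library 10. FZD5 had 0.79 without WNT5A libraries 4, 12 and 14, and 0.20 without these and the same 3 controls.

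Of 15 tested WNT receptors and co-receptors, 14 had a higher fitted value, against 62.3% of all tested genes, and none passed, with the smallest p for LRP6 (0.35) and LGR5 (0.42), which had -0.16 and 0.06 after quantile normalization. The list median was 0.24 above that of all genes (camera adjusted p = 0.517), and went from 0.35 to 0.04 both after quantile normalization and without control libraries 2, 3 and 6. Planar cell polarity and non-canonical transducers (16 of 22 higher) were led by SCRIB (0.73) and MAP2K4 (0.39), with camera adjusted p = 0.784. The calcium branch (13 of 18 higher) was led by PPP3R1 (0.74) and CAMK2G (0.98), with camera adjusted p = 0.697. In WNT5A libraries 4, 12 and 14 SCRIB averaged 8.07 and CAMK2G 8.25 RPKM, against 2.97 and 2.01 in the other 5, and without these 3 and control libraries 2, 3 and 6 their log2 changes were 0.10 and 0.20, and that of PPP3R1 was 0.39 (0.21 after quantile normalization). Among 15 beta-catenin targets, TRIB2 (0.78) and BAMBI (-0.58) had the smallest p (-0.16 for BAMBI without control libraries 2, 3 and 6, and 0.10 for TRIB2 without these and WNT5A libraries 4, 12 and 14), and the list gave camera adjusted p = 0.721.

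Lineage genes showed no change past the threshold. The pluripotency factor POU5F1 was abundant, at 1953 ± 224 RPKM in controls (SD, n = 9) and 1706 ± 431 in WNT5A pools (SD, n = 8), with a log2 change of -0.23 ± 0.15 (SE; limma adjusted p = 0.721). In WNT5A libraries 4, 12 and 14 it averaged 1193 RPKM, and in the other 5 2014 RPKM, and without these 3 libraries its log2 change was 0.05. NANOG had a log2 change of 0.63 ± 0.50 (SE; limma adjusted p = 0.753), averaged 9.88 RPKM in these 3 libraries and 5.79 in the other 5, and had 0.39 without these 3. The trophectoderm factor CDX2 stood at 30.2 ± 13.2 RPKM in WNT5A pools (SD, n = 8), a log2 change of 0.00 ± 0.26 (SE), and the primitive endoderm factor GATA6 at 288 ± 93.8 in WNT5A pools (SD, n = 8) and 293 ± 119 in controls (SD, n = 9). GATA3, a trophectoderm transcription factor, had a log2 change of 0.94 ± 0.53 (SE; limma adjusted p = 0.698), which was 0.26 without control libraries 2, 3 and 6. CDX2 had -0.19 and GATA6 -0.25 without these controls. SOX2 and XIST were not analysed here.

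Of 20 tested pluripotency and epiblast genes, 15 had higher fitted values, and KLF2 passed when adjusted over the list alone (limma adjusted p = 0.0251). Adjustments over a list alone were not corrected over the 36 lists, in which 4 genes passed so. The de novo DNA methyltransferase gene DNMT3B had a log2 change of 1.17 ± 0.40 (SE) and did not pass in that way (adjusted p = 0.0741). It averaged 33.2 RPKM in WNT5A libraries 4, 12 and 14, which was 2.37 times its mean in the other 5. In control libraries 2, 3 and 6 it averaged 3.58 RPKM, against 12.2 in the other 6 controls, and without WNT5A libraries 4, 12 and 14 and control libraries 2, 3 and 6 its log2 change was 0.18. In WNT5A libraries 4, 12 and 14 KLF2 averaged 3.63 RPKM, against 1.53 in the other 5. Without these 3 and control libraries 2, 3 and 6 its log2 change was 0.68, against 1.12 with all libraries. The list gave camera adjusted p = 0.517. Trophectoderm genes (18 of 24 higher) were led by KRT18 (0.43) and GATA2 (0.66), with camera adjusted p = 0.524, and primitive endoderm genes (17 of 21 higher) by BMP2 (0.70) and RSPO3 (0.41), with camera adjusted p = 0.517. BMP2 averaged 0.0240 RPKM in control libraries 2, 3 and 6 and 2.25 in the other 6 controls, and without these 3 its log2 change was 0.17 and the median of the primitive endoderm list -0.02. Without these controls and WNT5A libraries 4, 12 and 14, GATA2 had -0.02 and RSPO3 0.06.

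Among 38 tested genes of compaction, junctions and polarity, 30 had higher fitted values, and CLDN7 passed when adjusted over the list alone (adjusted p = 0.00325), while CLDN1 had a log2 change of 0.77 (0.10 without WNT5A libraries 4, 12 and 14 and control libraries 2, 3 and 6). The list gave camera adjusted p = 0.329, and adjusted p = 0.846 with an estimated correlation. It passed without WNT5A libraries 4, 12 and 14 (camera adjusted p = 0.0146, and adjusted p = 0.841 with an estimated correlation), but not without control libraries 2, 3 and 6 (0.915) or without all 6 (0.493). In the Hippo pathway list 20 of 25 were higher, AMOTL1, an angiomotin family gene, passed when adjusted over the list alone (adjusted p = 0.0149), and CCN1 had a log2 change of 0.96 (list camera adjusted p = 0.524). CCN1 averaged 0.0294 RPKM in control libraries 2, 3 and 6, and 6.61 in the other 6 controls. It averaged 3.31 RPKM in WNT5A libraries 4, 12 and 14 and 8.63 in the other 5 (6.63 over all WNT5A pools). Its log2 change was 0.06 without these 3 controls, 1.43 without these 3 WNT5A libraries and 0.53 without all 6. Of 23 TGF-beta and BMP genes 19 were higher, led by the inhibitory SMAD7 (1.13) and by SMAD1 (0.92), with camera adjusted p = 0.207. Without control libraries 2, 3 and 6 SMAD1 had 0.35, and the list median, 0.28 with all libraries, was -0.00456 (-0.02 after quantile normalization). In WNT5A libraries 4, 12 and 14 SMAD7 averaged 22.3 and AMOTL1 4.38 RPKM, against 7.75 and 1.89 in the other 5. Without these 3 and control libraries 2, 3 and 6 the log2 change of SMAD7 was 0.29. That of AMOTL1 was then 0.55, against 1.13 with all libraries.

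Cytosolic ribosomal protein genes were lower relative to other genes in WNT5A pools, with 64 of 75 below 0 and a median 0.31 below that of all genes (camera adjusted p = 1.7e-09). Nuclear-encoded oxidative phosphorylation genes were likewise lower, with 41 of 48 below 0 and a median 0.29 below (camera adjusted p = 2.1e-07). Both calls were lost with an estimated correlation (adjusted p = 0.846 for each list). No member passed as a single gene, and RPS19 (-0.50), RPLP2 (-0.49), COX5B (-0.46) and COX6B1 (-0.55) had the smallest p. Without control libraries 2, 3 and 6, where RPS19 averaged 525 RPKM against 320 in the other controls, neither list passed (camera adjusted p = 0.702 and 0.536). Neither passed after quantile normalization (camera adjusted p = 0.142 and 0.691), when their medians were -0.07 and -0.04 and that of all genes -0.01. The blood and immune cell list had 5 tested members, 4 of them lower (camera adjusted p = 0.0288, and adjusted p = 0.265 with an estimated correlation). Of these AIF1 had a log2 change of -1.18 and passed when adjusted over the list alone (limma adjusted p = 0.0419), and the alpha globin gene HBA had -0.53. Without control libraries 2, 3 and 6 AIF1 had -0.72 and HBA -0.30. Without these and WNT5A libraries 4, 12 and 14 AIF1 had -0.38 and HBA -0.18. AIF1 averaged 0.0282 RPKM in WNT5A libraries 4, 12 and 14 and 1.03 in the other 5. That list did not pass without control libraries 2, 3 and 6 (camera adjusted p = 0.121), without WNT5A libraries 4, 12 and 14 (0.105) or with no filter (0.208). Its call was also lost when any one of 6 libraries was left out, namely controls 2, 10 and 13 and WNT5A libraries 4, 10 and 14 (camera adjusted p = 0.0574 to 0.0843). These were the only 3 of 36 tested lists that passed.

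**Figure D3:**
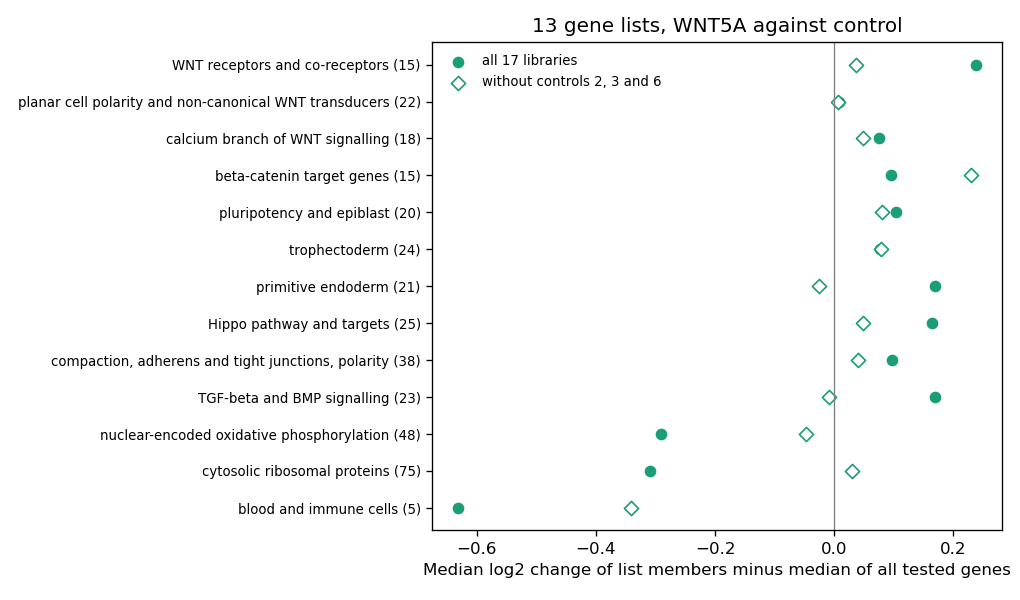
Median log2 change of the tested members of 13 gene lists (number of members in brackets) minus the median of all tested genes in the same fit, with all 17 libraries (filled circles) and without control libraries 2, 3 and 6 (open diamonds). Ribosomal protein genes move from 0.31 below the median of all genes to about that median when these controls are left out.

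The authors' deposited table, from a likelihood ratio test per gene, listed 173 genes at FDR under 0.05, all of them higher with WNT5A. The smallest FDR of a lower gene in the authors' deposited table was 0.114. SCML2, a polycomb group gene, and ENSBTAG00000051364 shared the smallest FDR in the authors' deposited table, 9.4e-08, and the laminin gene LAMB3 (FDR = 0.000101) and the drug-metabolising enzyme gene CYP3A4 (FDR = 0.000233) were also near the top. Of these 173 genes, 144 averaged under 1 RPKM in WNT5A pools, 70 had no read in any control, and 158 were not expressed highly enough to enter the limma test. SCML2 averaged 0.662 ± 0.686 RPKM (SD, n = 8), with reads in 8 WNT5A pools and 1 control. Of 154 genes on the WNT lists, 4 were among the 173, namely MCAM, DVL1, MAPK10 and NKD2, where 1.55 were expected (Fisher's exact test, two-sided, p = 0.0705).

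Between WNT5A libraries 4, 12 and 14 and the other 5, 18 of the 173 genes were higher and 1 was lower (limma, adjusted over the 173). Of the 12415 tested genes, 2419 differed between the same libraries, 985 higher and 1434 lower in the 3 (limma, adjusted p under 0.05). By their means 98 of the 173 were higher in these 3 libraries and 75 lower, and 16 had no read in any of the 3. Among the 29 listed genes that averaged at least 1 RPKM in WNT5A pools, a level that some reached through these 3 libraries, 19 were higher in WNT5A libraries 4, 12 and 14 than in the other 5 (limma, adjusted over these 29), and none was lower. MIF, a cytokine gene, averaged 308 RPKM in those 3 libraries, 12.3 in the other 5 and 9.67 in controls. DVL1, an intracellular transducer of WNT signals, averaged 4.50, 0.195 and 0.0407 RPKM in the same order, and the histone demethylase gene KDM6B 6.17, 0.327 and 0.209. IGFBP2, an insulin-like growth factor binding protein gene, averaged 933, 238 and 171 RPKM. KHDRBS3 was not among these 19 of the 29 genes (60.4, 50.9 and 30.4 RPKM, limma adjusted p = 0.108 over the 29). CLDN7 was among them (67.5, 29.4 and 15.5 RPKM, limma adjusted p = 0.0214 over the 29). This set differs from the genes that passed when adjusted over all 173, of which 18 were higher and 1 was lower.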

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

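Of the tests weighed here, those on 100 drawn splits, on splits of the WNT5A libraries for all tested genes and on thinned reads were set before their result was seen; the others were chosen after. Counts of splits include the real one. Within-group spread was tested in 128 groups by Dixon's ratio, the gap next to an extreme library over the group's range. Of these, 17 held a library far from the others, where 1 in 20 is about 6.4. That rate assumes normally distributed values in independent groups, which genes at 0 in most libraries do not give. For ROR1 all other controls were 0, so that any single control with reads would be flagged. No excess over chance is drawn from the 17.

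Library 12 of the WNT5A group was high in the share of its 10 most abundant genes (14.4%). Control library 6 was low on principal component 2 (-99.3) and in RYK (1.10), all gene values here being log2(RPKM + 1). Control library 5 was high in ENSBTAG00000027786 (2.52), ROR2 (0.89), SNORD15 (2.27) and SIX2 (0.82). Control library 3 was high in WNT5A (2.82), and control library 9 in ROR1 (0.20). Control library 10 was low in AXIN2 (0.21), control library 2 in GATA3 (0.12) and SNX17 (2.56), and control library 13 in KHDRBS3 (3.62). Among WNT5A libraries, library 1 was high in ROR2 (1.22), library 10 low in AXIN2 (2.67), library 7 low in PLBD1 (0.97) and library 4 high in SNORD15 (3.40).

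Of 173 genes called in the authors' deposited table, 18 were higher and 1 lower in WNT5A libraries 4, 12 and 14 than in the other 5 (limma, adjusted over the 173). WNT5A acting alike in all 8 pools, as the only cause, is argued against for these 19 of the 173 genes. Of 56 splits of the WNT5A libraries into 3 and 5, 1 passed as many, and the highest other split passed 1. For the other 154 genes that cause remains open. Between these 3 libraries and the other 5, 2419 of the 12415 tested genes differed (limma, adjusted p under 0.05), 985 higher and 1434 lower in the 3. The difference was therefore not particular to the 173 genes. Other splits gave at most 1 such gene, so that 1 of 56 splits reached this number, which argues against chance. A separate library batch and a response of these 3 pools that differed from the other 5 cannot be told apart for these 19 of the 173 genes. These libraries were all of the WNT5A group, and the labels give no batch.

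Genes detected in at least 5 WNT5A pools and at most 1 control numbered 186. No gene showed the reverse, for which a similar share of the controls and at most 1 WNT5A pool were required. Depth is argued against, since 178 such genes were counted after each library was thinned to 34.0 M reads. A difference in genes detected per library may account for the 186: simulated tables with only gene and library effects gave a median of 168. They reached 186 in 7.5% of 200 draws. The same tables gave a median of 0 genes for the reverse, so the lack of such genes does not point to WNT5A. For the grouping itself, 3 of 100 drawn splits were as large (highest other 211), under the 5 set beforehand. Of all 24310 splits, 473 were as large (1.95%). These shares are low but were not adjusted over the patterns tested. Genes detected per library did not differ past the threshold either (exact permutation adjusted p = 0.170), so chance is not excluded. The highest of all splits gave 561, which points to a structure of the libraries other than their group. Whether WNT5A or sample quality set the genes detected per pool was not tested.

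Ribosomal protein and oxidative phosphorylation lists were lower with WNT5A. Control libraries 2, 3 and 6 may account for this, as the smaller adjusted p of these lists was 0.536 without them. Members varying together between libraries may too, with a smaller adjusted p of 0.846 under an estimated correlation. Chance cannot be excluded for the 3 lists called, since 52 of 100 splits called as many and the highest other split called 9. The tests used here leave an action of WNT5A on these genes open.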

How the results depend on the processing

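Alternatives that left out sets of libraries, lists on 8 libraries without the block, the fit on recovered reads and those joining no filter with pseudocount 0.1 were chosen after seeing the data; the others were planned. The planned count tests were not run, since the values are RPKM. The cause of each change below was not tested.

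ENSBTAG00000027786 remained the 1 gene called with a stricter filter, pseudocount 0.1, no robust option, a residual principal component, library weights or a threshold of 0.10. The number called was 0 with no filter, quantile normalization or median centring, 0 without control libraries 2, 3 and 6, without WNT5A libraries 4, 12 and 14 or without all 6, and 0 with limma-voom on recovered reads (913 genes had an unadjusted p under 0.05 in limma). Leaving out each library gave 0 to 2. With no filter and pseudocount 0.1, it was 3 (3 with no robust option), 0 in every form without the 3 controls, 11, 12, 13 or 18 without the 3 WNT5A libraries, and 4, 4, 5 or 6 without all 6, each set of numbers covering robust or not and genes at 0 removed or kept. Over its 36 alternatives the limma adjusted p of ENSBTAG00000027786 was 1.1e-04 to 0.9999. Its log2 change was 1.70 to 2.39 on the log2(RPKM + 1) scale, and on other scales 4.06 to 4.59 with pseudocount 0.1 and 7.34 on recovered reads.

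Title numbers 1, 2, 4 and 10 occur in both groups. The labels do not say that these numbers pair pools, so the main fit did not use them. Deviations of same-numbered libraries correlated at 0.22, 0.06, 0.02 and 0.11, not all over 0.1. The 2 lower values were for numbers 2 and 4, which hold control library 2 and WNT5A library 4, both set apart above. As 5 of 8 libraries correlated best with their own number, where chance gives 2, pairing was left open. On these 8 libraries 0 genes were called with the replicate number as a block and 0 without it, and 2 lists were called with the block and 0 without it. The blood and immune list was not called in either (camera adjusted p = 0.0828 and 0.119). FZD5 (-0.15), CDX2 (-0.068) and GATA6 (-0.38) reversed both with and without the block.

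Lists called numbered 3, and were 0 with an estimated correlation (also without WNT5A libraries 4, 12 and 14), with fry, without control libraries 2, 3 and 6, without all 6 libraries and on these 8 without the block, and 2 to 4 in the others. Of the 3 called after quantile normalization 1 was shared, the blood and immune list. Without WNT5A libraries 4, 12 and 14 4 were called, 2 of them shared, and mitochondrially encoded genes were lower (camera adjusted p = 4.0e-08, and adjusted p = 0.841 with an estimated correlation); these did not pass with all libraries (0.970, higher), without control libraries 2, 3 and 6 (0.0630, higher) or without all 6 (0.133, lower). Without control libraries 2, 3 and 6 ribosomal protein genes turned higher (camera adjusted p = 0.702), and without all 6 oxidative phosphorylation genes did (0.863).

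Of 1866 single-gene alternatives over 52 named genes, 1793 kept direction and side of the threshold, 28 lost the call of ENSBTAG00000027786, 1 gained it (SNORD15 without control library 5), and 44 reversed, in 8 genes. LRP6 was -0.16 after quantile normalization, and CDX2 -0.076 and GATA6 -0.054 after centring. Without control libraries 2, 3 and 6, RYK was -0.10, FZD5 -0.21, CDX2 -0.19 and GATA6 -0.25, and with no filter and pseudocount 0.1 -0.11, -0.25, -0.20 and -0.25. Without WNT5A libraries 4, 12 and 14 POU5F1 was 0.051 in both forms. Without all 6, RYK was -0.15, CDX2 -0.15, POU5F1 0.085 and GATA2 -0.021, and with no filter and pseudocount 0.1 -0.16, -0.16, 0.085 and -0.020. Leaving out each library, RYK ranged from -0.046 to 0.31, AXIN2 from -0.24 to 0.29, CDX2 from -0.14 to 0.12 and GATA6 from -0.11 to 0.12.

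The share of the 10 most abundant genes lost its call on ranks (rank difference 5.43), without control libraries 2, 3 and 6 (1.92 points), without WNT5A libraries 4, 12 and 14 (0.30) and when any of 13 libraries was left out; it held only without control 4 or WNT5A libraries 2, 7 or 10, and ranged from 1.09 without WNT5A library 12 to 2.32 points. Without WNT5A libraries 4, 12 and 14 the differences in reads (19.6 M), mitochondrial share (-0.31 points), principal component 2 (4.18) and cumulus genes (0.14) reversed, none past the threshold. Leaving out each library, principal component 2 ranged from -13.1 to 9.48 and cumulus genes from -0.11 to 0.041.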

Other observations

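All genes, those that the expression filter removed included, were tested after the data were seen, with no filter and a pseudocount of 0.1. SCML2, ENSBTAG00000027786 and FBXL17 passed (limma adjusted p = 0.0286, 0.0286 and 0.0381), all higher with WNT5A. SCML2 had a log2 change of 2.58 ± 0.40 (SE) on this scale. Without WNT5A libraries 4, 12 and 14, 11 genes passed, all higher with WNT5A, and the number was 11 to 18 over the forms of the fit that were tried. These included UPK2, a urothelial membrane protein gene (2.86 ± 0.31, SE), the ciliary gene CYS1 (3.15 ± 0.34), RASSF9 (2.20 ± 0.28), CYP3A4, PDYN, TRIM44 and PAQR8. UPK2 and CYS1 had reads in all 5 of the WNT5A libraries with more reads and in no control, at 0.582 ± 0.467 and 0.651 ± 0.504 RPKM over all WNT5A pools (SD, n = 8). Each had reads in only 1 of WNT5A libraries 4, 12 and 14, which this fit left out. As every control was 0, the size of their log2 changes depends on the pseudocount, and the controls added no spread. Both are among the 186 genes above, for which a difference in genes detected per library may account. Without control libraries 2, 3 and 6 none passed, and without all 6 libraries SCML2, UPK2, CYS1 and ENSBTAG00000046739 did.

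For the count of genes past the threshold, chance cannot be excluded. The real split gave 1 gene, 6 of 100 splits, the real one included, gave as many, and the highest other split gave 54. At an unadjusted p under 0.05 the real split gave 913 genes, 13 of 100 splits, counted in the same way, gave as many, and the highest other gave 2389, which points to a structure of the libraries other than their group.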
